A study of Mus musculus with 6 samples.

How the data were processed

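RNA was sequenced from inguinal white adipose tissue, a subcutaneous fat depot, of mice fed a high-fat diet for 15 weeks from 8 weeks of age. The 6 samples form 2 groups of 3, control samples from mice with a floxed Cdo1 gene and samples from Cdo1AKO mice, in which Cdo1 was deleted in adipose tissue. Groups and replicate numbers came from the sample titles. The labels name the controls WT in their genotype field, and the table's WT columns were matched to the control titles by that field and the number. Per the labels' protocols, RNA was isolated with TRIzol and libraries were made with a NEBNext Ultra kit; no strand setting is given in the sources used here, so reads of overlapping and antisense genes cannot be told apart.

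The authors deposited 1 table with raw counts per gene for each sample, per the file headers. HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.20.0 and the build mm10 are listed in the submitters' processing notes, without roles. The table also holds FPKM values deposited by the authors and, per the file headers, their comparison of Cdo1AKO with WT as log2 fold changes, p-values and adjusted p-values. FPKM was used only to find its scale. It equals the count per kilobase of the listed gene length divided by 1 constant per library, from 15.7 to 20.1 when the library size is counted in units of 1000000 reads, which differs from the library's total. Coordinates are those of the table.

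Total counts were 17830940, 17959740 and 19205804 in control 1 to 3 and 17965163, 18065810 and 16275184 in Cdo1AKO 1 to 3. Of 54532 genes, 16623 passed edgeR's filterByExpr by group and were tested. Counts were scaled with TMM factors and tested with edgeR 4.0.16 (quasi-likelihood fit, group as the only term, default settings) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values use the TMM-scaled library sizes, SE is the standard error of the log2 fold change, and SD is over the 3 libraries of a group. Gene lists for pathways, RNA quality and cell types were fixed before the data were examined, as were the main test and the rule for named genes. Lists with at least 5 tested members (42) were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 42 lists, with Cdo1 left out of every list. Where a symbol names 2 genes, the copy with more counts entered its list. The mesothelium list had 4 tested members and was not tested.

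Named genes were Cdo1, Pparg, Med24, Pnpla2, Lipe, Ucp1, Lep and Adipoq whatever their result. The second part took up to 8 higher and 8 lower protein-coding genes with adjusted p under 0.05, mean CPM of at least 5 and no overlap between the groups. The last part took, by smallest p, 3 members of each list that passed and 2 members of each other list described. Some genes that these rules name are not reported here. No gene met the second part. The same criteria were therefore also read on the authors' deposited table and on a fit with a lymph node term, both chosen after the values were seen. That term marks libraries in which the median CPM of the lymph node stroma and B cell markers, without immunoglobulin genes, was above 5.

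The edgeR test and camera with the preset correlation were tested on simulated counts with 200 changed genes, in 1 draw per design. Counts were drawn gene by gene from the tested genes' means and dispersions, so correlation between genes was not simulated. The other methods were not simulated. With group as the only term, 0 of 67 genes changed 1.5-fold, 0 of 67 changed 2-fold and 3 of 66 changed 4-fold were recovered, since the libraries of a group differ widely. With the lymph node term these were 1 of 67, 21 of 67 and 58 of 66, with 5 calls among unchanged genes. Alternatives were other scaling factors, other filters, DESeq2 1.42.0, limma-voom, robust estimation, a replicate block, each sample left out, and camera with estimated correlation or fry for lists. Nothing in the labels says that the samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.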

Results

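Bulk RNA sequencing compared 3 control and 3 Cdo1AKO samples of inguinal white adipose tissue from mice on a high-fat diet, with 16275184 to 19205804 counts per library. The comparison asks how the adipose transcriptome differs when Cdo1, which encodes cysteine dioxygenase 1, the enzyme that oxidises cysteine on the route to taurine, is deleted in adipose tissue.

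Cdo1 (ENSMUSG00000033022, mm10 chromosome 18, 46713205 to 46728342, minus strand) had 887, 432 and 631 CPM in control 1 to 3 and 123, 392 and 134 CPM in Cdo1AKO 1 to 3. Every Cdo1AKO library lay below every control library, and Cdo1AKO 2 came close to control 2. The log2 fold change -1.59 ± 0.53, adjusted p = 0.416 (SE, 3 libraries per group) did not pass the edgeR test, and it was -2.33 without Cdo1AKO 2. Cdo1 also did not pass with DESeq2 (adjusted p = 0.0867) or in the authors' deposited comparison (adjusted p = 0.0825). Which exons were floxed is not given in the sources used here, so counts from exons that remain are possible, as are counts from cells other than adipocytes.

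As lists, genes of adipocytes, lipolysis, fatty acid oxidation, the circadian clock and Schwann cells were lower in Cdo1AKO, and genes of T cells and natural killer cells, dendritic cells, macrophages, extracellular matrix, the cell cycle and skeletal muscle were higher. The medians ran from -0.79 for Schwann cell and nerve markers to 1.71 for T cell and natural killer cell markers on the log2 scale. These calls rest on camera with a preset correlation (25 of 42 lists), and 0 lists passed with an estimated correlation. Several of the higher calls also rest on single libraries. Without Cdo1AKO 2 the matrix list turned direction, and the macrophage and cell cycle calls were lost. The T cell and dendritic cell calls were lost without control 1, Cdo1AKO 1 or Cdo1AKO 3. The skeletal muscle call and the lower calls named here stayed without each library. Over all genes 0 passed the edgeR test, with 1724 at an unadjusted p under 0.05, and DESeq2 called 271.

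Transcripts of lymph node and B cells separated the libraries more than the genotype did. Ms4a1, a B cell surface protein, had 0.0614 CPM in control 1 and 0.901 CPM in Cdo1AKO 2, and 75.8 to 143 CPM in the other 4 libraries. Glycam1, made by the high endothelial venules of lymph nodes, had 0 CPM in those 2 libraries and 20.9 to 37.4 CPM in the other 4. The first principal component, which set these libraries apart, held 69.2% of the variance. Each group had 1 library without and 2 libraries with these transcripts. Neither the B cell and plasma cell list (18 tested, median -0.14, adjusted p = 0.848 by camera, and adjusted p = 0.962 with an estimated correlation) nor the lymph node stroma list (9 tested, median -0.12, adjusted p = 0.873 by camera, and adjusted p = 0.962 with an estimated correlation) passed. Ighm, the heavy chain of IgM, had 755 ± 549 CPM against 266 ± 237 CPM (SD, n = 3), and Jchain a log2 fold change of -0.88 ± 0.78 (SE). Tnfsf11 had 2.69 ± 2.17 CPM against 1.59 ± 1.41 CPM (SD, n = 3), and the chemokine Cxcl13 a log2 fold change of -0.69 ± 1.44. None of these passed. Without control 2 the log2 fold changes were 2.26 for Ighm, -0.26 for Jchain, 1.53 for Tnfsf11 and 0.13 for Cxcl13, and without Cdo1AKO 2 that of Ighm was 0.72.

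**Figure D1:**
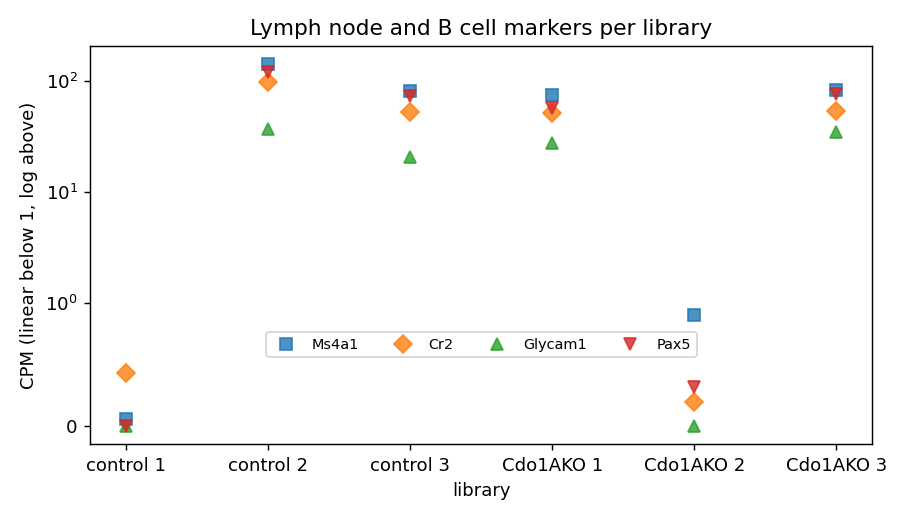
CPM of 4 lymph node and B cell markers (y axis, linear below 1 and logarithmic above) in each of the 6 libraries (x axis), 1 point per gene and library. Control 1 and Cdo1AKO 2 lie near 0, with Ms4a1 at 0.0614 and 0.901 CPM, and the other 4 libraries lie above.

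The libraries of a group were also unevenly alike. Counts of Cdo1AKO 1 and 3 differed by 5.59 times the sampling variance, a chi-square per gene, against 23.1 to 81.5 times for pairs of controls and 196 to 204 times for Cdo1AKO 2 with the others of its group. All pairs differed by more than sampling noise, which speaks against a library deposited more than once but does not show that the libraries came from separate animals. Each library was counted as 1 sample.

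Across all genes, 0 passed the edgeR test at adjusted p under 0.05, with 0.196 the smallest adjusted p. At an unadjusted p under 0.05 there were 1724 genes, 774 higher and 950 lower in Cdo1AKO. Limma-voom called 0 and DESeq2 called 271, with 94 higher and 177 lower. The authors' deposited table holds 275 genes at adjusted p under 0.05, with 95 higher and 180 lower, and 270 of them were among the DESeq2 calls. Of genes named in this report, those 275 include Acta2, Adrb3, Hcar2, Pnpla2, Irs1, Ppara and Ppargc1a. Cdo1, Lipe, Adipoq and Pparg were not among them. With the lymph node term, chosen after seeing the data, edgeR called 686 genes, 375 higher and 311 lower, among them Cdo1 (log2 fold change -1.76 ± 0.25, adjusted p = 0.0256). Within the 4 libraries with lymph node transcripts it called 2617, while the 2 libraries without them are 1 per group and allow no test. With Cdo1AKO 1 and 3 summed as 1 sample and control 3 left out, the same term called 0 genes, with 1264 at unadjusted p under 0.05. The smallest adjusted p of that fit was 0.512 by edgeR. It has so few samples for its terms that its 0 calls decide nothing about the 686 genes.

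The criteria for named genes, among them mean CPM of at least 5 and no overlap between the groups, were read on the authors' deposited table. Of the genes that met them there, the lower ones with the largest change included Cyp2f2 (-4.13, adjusted p = 2.35e-07) and Cyp2e1 (-2.79, adjusted p = 8.32e-05), both cytochrome P450 enzymes. Others were Acsm3 (-2.64, adjusted p = 0.00178), the adipsin gene Cfd (-2.16, adjusted p = 1.01e-04), Celsr2, Osbp2 and the thiosulfate sulfurtransferase Tst (-1.95, adjusted p = 9.84e-04). By the same criteria, the higher genes with the largest change there were the oxytocin receptor Oxtr (3.82, adjusted p = 4.62e-05), Lipf (3.11, adjusted p = 0.00217), Mogat2, Tfr2, Ncan, Scn8a, Kcnj14 and Atp1a4. Oxtr stood at 286 CPM in Cdo1AKO 2, 48.8 and 47.3 CPM in Cdo1AKO 1 and 3, and 9.01 ± 3.87 CPM (SD, n = 3) in controls. Without Cdo1AKO 2 the edgeR log2 fold changes of the higher genes, with group as the only term, were smaller: Oxtr 2.41 from 3.82, Lipf 1.88 from 3.10, Mogat2 1.32 from 2.98, Tfr2 1.99 from 2.98, Scn8a 1.71 from 2.88, Kcnj14 1.37 from 2.78 and Atp1a4 1.54 from 2.46. Ncan stood at 56.2 CPM in Cdo1AKO 2 and at 7.50 and 6.26 CPM in Cdo1AKO 1 and 3. Without control 1 Cyp2f2 was at -3.35 from -4.12 and Cyp2e1 at -2.19 from -2.79. Read on the edgeR fit with the lymph node term, these criteria gave Cdkl4, Col16a1, Pcolce2, Zfp949, Fscn1, C6, Adam8 and Bicdl1 as the higher genes with the largest change. The lower ones included Cyp2f2, Cyp2e1, Celsr2, Osbp2, Slc1a3, Tst and Ces1f. Pcolce2, with 2.46 by group only, was at 1.33 without Cdo1AKO 2. In that fit the actin-bundling gene Fscn1 had log2 fold change 1.89 ± 0.15, adjusted p = 0.0174, and the carboxylesterase gene Ces1f -1.85 ± 0.17, adjusted p = 0.0222.

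Genes of adipocytes and of fat storage and use were lower in Cdo1AKO as lists. Values given for genes without a unit are log2 fold changes of Cdo1AKO over control ± SE, from 3 libraries per group. Of 42 lists, 25 passed camera with the preset correlation, 13 lower and 12 higher, and 0 passed with an estimated correlation; fry called 1. The 3 lists fixed as signs of RNA quality and handling also passed camera: mitochondrially encoded mRNAs were lower (adjusted p = 0.0103), and cytosolic ribosomal proteins (0.00206) and immediate early and dissection stress genes (0.00668) were higher. With an estimated correlation these had adjusted p = 0.672, 0.711 and 0.575. The PPARG target and adipocyte differentiation list (30 tested, 24 with a negative fold change) had a median of -0.43 (adjusted p = 2.59e-07 by camera, and adjusted p = 0.594 with an estimated correlation); 0 members fell when adjusted over the list alone or over all genes. Cfd was at 2184 ± 779 CPM against 9781 ± 3799 (SD, n = 3), the glucose transporter Slc2a4 had -1.10 ± 0.32 and the fatty acid transporter Slc27a1 -1.09 ± 0.33 (log2 fold change, SE). The adipocyte marker list (16 tested) had a median of -0.44 (adjusted p = 4.89e-06 by camera, and adjusted p = 0.577 with an estimated correlation), and 3 members fell adjusted over the list alone, Adrb3, Acvr1c and Cfd. The beta-3 adrenergic receptor Adrb3 was at 147 ± 46.8 CPM against 508 ± 59.5, a log2 fold change of -1.79 ± 0.28. Adipoq (-0.42 ± 0.35) and Pparg (-0.44 ± 0.32) did not pass. Lep had 1.24 ± 0.73, which rests on Cdo1AKO 2 at 8301 CPM; without that library it was -0.070.

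The lipolysis list (22 tested, 16 negative) had a median of -0.33 (adjusted p = 4.89e-06 by camera, and adjusted p = 0.577 with an estimated correlation). Adjusted over the list alone 4 members fell and over all genes 0. The niacin receptor Hcar2 had -1.29 ± 0.17, Adrb3 -1.79 ± 0.28 and Adrb1 -1.05 ± 0.22. Pnpla2, which encodes adipose triglyceride lipase, was at 2146 ± 210.3 CPM against 4591 ± 1376 (SD, n = 3). Its log2 fold change was -1.10 ± 0.35 (adjusted p = 0.396 by edgeR), and hormone-sensitive lipase Lipe had -0.71 ± 0.33. In the authors' deposited comparison Pnpla2 had adjusted p = 0.0224 and Lipe 0.326. Triglyceride synthesis was lower as a list (19 tested, median -0.39, adjusted p = 1.10e-04 by camera, and adjusted p = 0.594 with an estimated correlation). Its 3 members that fell adjusted over the list alone were Gpam with -1.07 ± 0.22, Gpat4 with -1.18 ± 0.28 and Gpat3 with -1.21 ± 0.30, all acyltransferases of glycerolipid synthesis. Fatty acid oxidation was lower as a list (24 tested, 21 negative, median -0.45, adjusted p = 8.00e-06 by camera, and adjusted p = 0.594 with an estimated correlation). It had 0 members that fell adjusted over the list alone, and Eci1 had -0.82 ± 0.21, Ehhadh -0.69 ± 0.20 and Slc25a20 -0.81 ± 0.25. De novo lipogenesis did not pass as a list (20 tested, median 0.33, adjusted p = 0.110 by camera, and adjusted p = 0.711 with an estimated correlation). Its median lay above 0 and its test direction below. Adjusted over the list alone 5 members fell, among them Acaca with -1.12 ± 0.22, the acetyl-CoA carboxylase, and Aacs with -1.33 ± 0.29. With the lymph node term the list passed on the lower side (adjusted p = 0.0198 by camera, and adjusted p = 0.644 with an estimated correlation).

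The respiratory chain list (43 tested, 40 negative) had a median of -0.29 (adjusted p = 4.68e-05 by camera, and adjusted p = 0.672 with an estimated correlation). Sdha had -0.61 ± 0.26, Ndufs7 -0.55 ± 0.25 and Sdhb -0.50 ± 0.25. All 21 members of the tricarboxylic acid cycle list were negative (median -0.29, adjusted p = 5.48e-04 by camera, and adjusted p = 0.672 with an estimated correlation). Suclg2 had -0.79 ± 0.20, Dlst -0.58 ± 0.25 and Idh2 -0.33 ± 0.19. Neither list had a member that passed adjusted over the list alone. Mitochondrially encoded mRNAs, a list fixed as a sign of RNA quality, were lower together with these mitochondrial lists (13 tested, median -0.27, adjusted p = 0.0103 by camera, and adjusted p = 0.672 with an estimated correlation). Among them mt-Co3 had -0.97 ± 0.39, mt-Nd3 -0.88 ± 0.38 and mt-Atp6 -0.67 ± 0.48 (-1.40 without Cdo1AKO 2). In CPM mt-Co3 stood at 21.0 in Cdo1AKO against 41.1 in controls, below Sdha at 399 against 611. Whether the list reads RNA quality at such levels was not tested. Thermogenic and beige adipocyte genes were lower as a list (20 tested, median -0.25, adjusted p = 0.0102 by camera, and adjusted p = 0.575 with an estimated correlation). Adjusted over the list alone 4 members fell. The coactivator Ppargc1a had -1.39 ± 0.21, Ppara -1.69 ± 0.25 and Ebf2 -1.60 ± 0.34. Ucp1 had 14, 17 and 9 counts in controls and 4, 8 and 5 in Cdo1AKO and was not tested. The calls of the mitochondrially encoded mRNAs were lost without Cdo1AKO 1 (adjusted p = 0.254) or 3 (adjusted p = 0.167), and that of the tricarboxylic acid cycle without Cdo1AKO 3 (adjusted p = 0.0625).

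**Figure D2:**
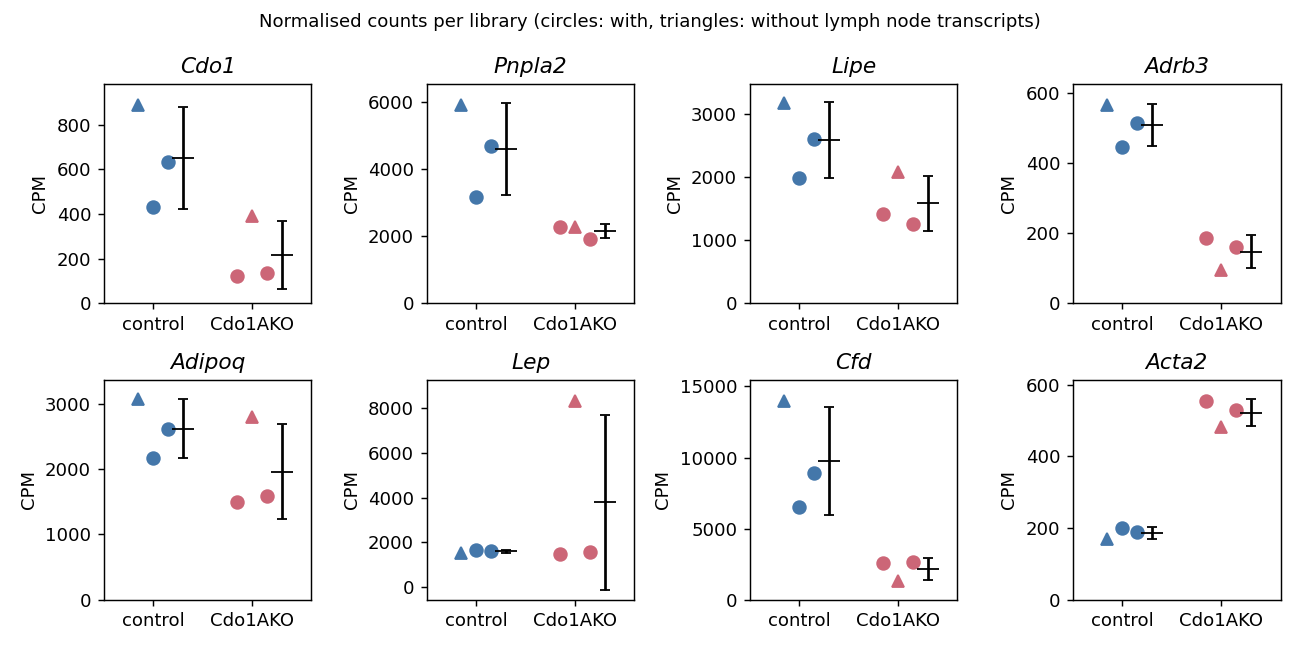
CPM (y axes, starting at 0, or below it for Lep where the SD bar crosses 0) of 8 named genes in the 3 control and 3 Cdo1AKO libraries (x axes), with mean and SD beside the points. Circles are libraries with and triangles libraries without lymph node transcripts. Adrb3 stood at 147 ± 46.8 CPM in Cdo1AKO and 508 ± 59.5 in controls, and Lep is high only in Cdo1AKO 2 among the 6 libraries.

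Insulin signalling and glucose uptake genes were lower as a list (22 tested, median -0.27, adjusted p = 4.51e-04 by camera, and adjusted p = 0.321 with an estimated correlation). The 2 members that fell adjusted over the list alone were the insulin receptor substrate Irs1 with -1.06 ± 0.14 and the insulin receptor Insr with -0.93 ± 0.20; Irs2 had -1.32 ± 0.35. The cysteine, taurine and glutathione list was lower (24 tested, median -0.22, adjusted p = 0.00315 by camera, and adjusted p = 0.577 with an estimated correlation). Adjusted over the list alone 5 members fell. Tst had -1.94 ± 0.39, Csad, which acts after Cdo1 on the taurine route, -1.04 ± 0.24, and the sulfide oxidase Sqor -1.01 ± 0.27. Circadian clock genes were lower as a list (19 tested, 15 negative, median -0.65, adjusted p = 6.13e-07 by camera, and adjusted p = 0.321 with an estimated correlation). Adjusted over the list alone 4 members fell, among them Hlf with -1.27 ± 0.20 and Tef with -0.95 ± 0.17, and Per3 was at 83.1 ± 14.9 CPM against 166 ± 16.1 (SD, n = 3). Schwann cell and nerve markers were lower as a list (12 tested, median -0.79, adjusted p = 1.72e-06 by camera, and adjusted p = 0.321 with an estimated correlation). Adjusted over the list alone 7 members fell. Cdh19 was at 3.02 ± 0.534 CPM against 9.28 ± 3.30 CPM (SD, n = 3; log2 fold change -1.62 ± 0.35, adjusted p = 0.309), and Mal had -1.84 ± 0.35.

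Lists that were higher in Cdo1AKO held genes of T cells and natural killer cells, dendritic cells, macrophages and the interferon response. Extracellular matrix, pericyte and smooth muscle, and skeletal muscle lists were higher too, among others. The B cell list and the neutrophil and mast cell list did not pass. T cell and natural killer cell markers (22 tested, median 1.71, adjusted p = 0.00662 by camera, and adjusted p = 0.672 with an estimated correlation) were higher as a list and varied with the lymph node transcripts. With the lymph node term the median of this list was 1.38 (adjusted p = 1.00e-12 by camera, and adjusted p = 0.433 with an estimated correlation). Foxp3, of regulatory T cells, had 1.92 ± 1.32 and, with the lymph node term, 1.91 ± 0.21 (adjusted p = 0.0222 by edgeR). Ccl5 had 2.21 ± 1.31 (2.85 without control 2) and Klrb1c 0.67 ± 0.37. In CPM Ccl5 stood at 220, 5.34 and 230 in Cdo1AKO 1 to 3 and at 6.01, 56.2 and 35.8 in control 1 to 3. Foxp3 stood at 24.3, 0.836 and 19.8 CPM against 0.245, 5.83 and 5.74 CPM. The high values of both genes were thus in Cdo1AKO 1 and 3, and in Cdo1AKO 2 both lay below controls 2 and 3. Klrb1c, at 1.80 CPM in Cdo1AKO 2, lay above controls 2 and 3. Dendritic cell markers were higher as a list (13 tested, all positive, median 0.58, adjusted p = 0.0103 by camera, and adjusted p = 0.672 with an estimated correlation). Cd209a had 0.99 ± 0.30, Itgae 2.06 ± 1.15 (2.79 without control 2) and Zbtb46 0.19 ± 0.12. Macrophage (18 tested, median 0.46, adjusted p = 0.00862 by camera, and adjusted p = 0.577 with an estimated correlation) and lipid-associated macrophage markers (15 tested, median 0.62, adjusted p = 0.0126 by camera, and adjusted p = 0.672 with an estimated correlation) passed on the higher side, with 0 members that passed adjusted over the list alone. Cd14 had -1.23 ± 0.30 against the direction of its list, Cd68 0.74 ± 0.22 and Csf1r 0.43 ± 0.13, and Tyrobp had 0.83 ± 0.19, Cd9 0.44 ± 0.13 and Trem2 1.57 ± 0.60 (0.84 without Cdo1AKO 2). Interferon response genes were higher as a list (28 tested, median 0.29, adjusted p = 0.0103 by camera, and adjusted p = 0.577 with an estimated correlation). Ifit2 had 0.59 ± 0.16, Bst2 0.32 ± 0.12 and, in the other direction, Ifi27l2a -1.13 ± 0.41. The calls of T cell and dendritic cell markers were lost without control 1 (adjusted p = 0.0776 and 0.377), without Cdo1AKO 1 (0.207 and 0.166) and without Cdo1AKO 3 (0.298 and 0.191). The macrophage call was lost without control 2 (0.0692) or Cdo1AKO 2 (0.170), and the lipid-associated macrophage call without Cdo1AKO 2 (0.725) and with the lymph node term (0.0565).

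The smooth muscle actin gene Acta2 was at 522 ± 37.2 CPM in Cdo1AKO against 186 ± 15.9 CPM in controls (SD, n = 3). Its log2 fold change was 1.49 ± 0.16 (adjusted p = 0.196 by edgeR). In the authors' deposited comparison Acta2 had adjusted p = 7.78e-12. It rose adjusted over the list alone in the extracellular matrix and fibrosis list (38 tested, median 0.64, adjusted p = 5.48e-04 by camera, and adjusted p = 0.672 with an estimated correlation) and in the pericyte and smooth muscle list (13 tested, median 0.27, adjusted p = 0.0126 by camera, and adjusted p = 0.594 with an estimated correlation), as 1 member of each. Among the others Thbs2 had -1.24 ± 0.28, Col14a1 0.83 ± 0.38, Notch3 0.53 ± 0.25 and Actg2 0.84 ± 0.40. Without Cdo1AKO 2 the matrix list turned to the lower side (adjusted p = 0.525), as it did within the 4 libraries with lymph node transcripts (0.820), and the pericyte call was lost (0.785). Skeletal muscle markers (11 tested, 10 positive, median 0.88, adjusted p = 1.70e-04 by camera, and adjusted p = 0.321 with an estimated correlation) were higher as a list. Casq1, the 1 member that rose adjusted over the list alone, was at 6.54 ± 1.45 CPM against 1.57 ± 0.927 CPM (SD, n = 3). Its log2 fold change was 2.05, and 2.64 without control 3. Pvalb had 3.08 ± 1.04 (1.61 without Cdo1AKO 2) and Tnnt3 0.94 ± 0.39. Both stood at low levels, Pvalb at 2.53 CPM against 0.288 CPM in controls and Tnnt3 at 1.66 against 0.860. Of the 21 muscle genes listed, only 11 passed the filter. The pericyte call was also lost without control 2 (adjusted p = 0.0911) or control 3 (0.0571), and the matrix call without control 2 (0.0547).

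Cell cycle genes were higher as a list (28 tested, all positive, median 0.42, adjusted p = 4.35e-04 by camera, and adjusted p = 0.672 with an estimated correlation). Ccnd1 had a log2 fold change of 0.82 ± 0.28, Cdk1 0.65 ± 0.31 and Ube2c 0.82 ± 0.49. Cholesterol synthesis was higher as a list (23 tested, median 0.62, adjusted p = 4.83e-04 by camera, and adjusted p = 0.633 with an estimated correlation). Mvd had 1.05 ± 0.33, Tm7sf2 0.82 ± 0.24 and, against the list's direction, Fdft1 -0.76 ± 0.22. Cytosolic ribosomal proteins, also a list of RNA quality, were higher (53 tested, median 0.26, adjusted p = 0.00206 by camera, and adjusted p = 0.711 with an estimated correlation). Rps27a had 0.72 ± 0.43, Rpl12 0.69 ± 0.46 and Rplp1 0.42 ± 0.28. Immediate early and dissection stress genes, the list for tissue handling, were higher (25 tested, median 0.46, adjusted p = 0.00668 by camera, and adjusted p = 0.575 with an estimated correlation). The 3 members that rose adjusted over the list alone were Ier2 with 0.95 ± 0.15, Nr4a1 with 1.01 ± 0.20 and Junb with 0.87 ± 0.20. Without Cdo1AKO 2 the calls of cell cycle (adjusted p = 0.0657), cholesterol synthesis (0.525) and immediate early genes (0.170) were lost, and within the 4 libraries with lymph node transcripts cholesterol synthesis turned direction (0.967). The cell cycle call was also lost without control 1 (0.367), the immediate early call without control 2 (0.0692), and the ribosomal call without control 3 (0.0640), Cdo1AKO 1 (0.211) or Cdo1AKO 3 (0.381).

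**Figure D3:**
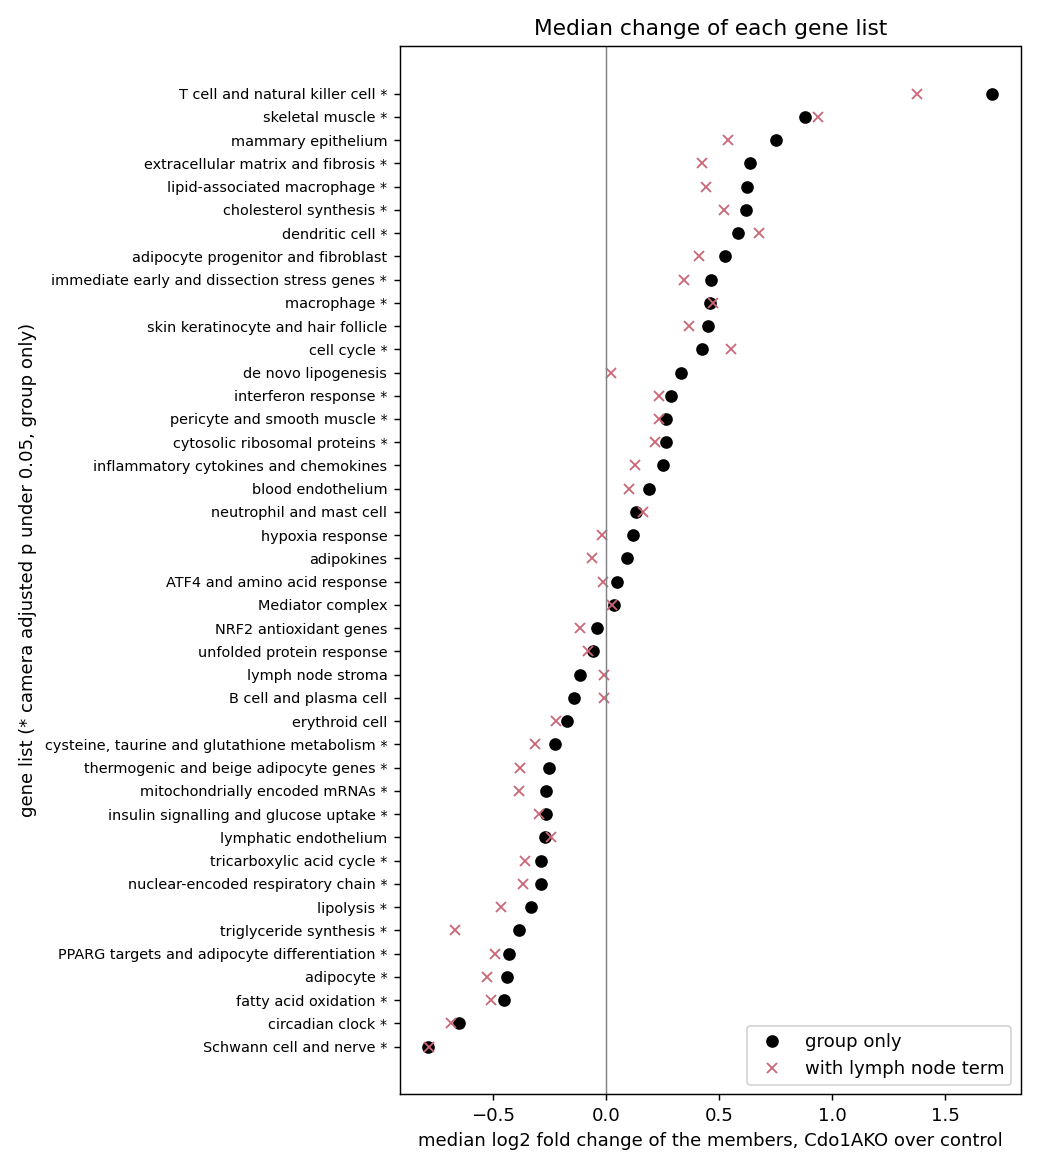
Median log2 fold change (x axis, Cdo1AKO over control) of the members of each of 42 gene lists (y axis). Black points are the fit with group only, crosses the fit with the lymph node term, and stars mark the 25 lists past the camera threshold with group only. The Schwann cell and nerve list has the median -0.79.

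The other lists did not pass camera, at the adjusted p given for each. Adipokines (19 tested, median 0.091, adjusted p = 0.0717) held 2 members that rose adjusted over the list alone, among them Sfrp5 with 1.05 ± 0.22, and 4 that fell, among them Nrg4 with -1.18 ± 0.17. With the lymph node term this list passed on the lower side (adjusted p = 0.0226 by camera, and adjusted p = 0.644 with an estimated correlation). Genes of the Mediator complex, a coactivator of transcription, had a median of 0.037 (29 tested, adjusted p = 0.809), and Med11 had 0.60 ± 0.19 and Med24 0.34 ± 0.16. In the ATF4 and amino acid response list (28 tested, median 0.048, adjusted p = 0.939), Asns had -1.45 ± 0.28 and Chac1 -1.53 ± 0.42. In the NRF2 antioxidant list (30 tested, adjusted p = 0.116), Gpx3 had -1.57 ± 0.50 and Nfe2l2 -0.35 ± 0.14. In the unfolded protein response list (24 tested, adjusted p = 0.238), Xbp1 had -0.85 ± 0.21 and Derl1 -0.73 ± 0.18. In the hypoxia list (23 tested, adjusted p = 0.579), Bnip3 had -0.94 ± 0.26 and Egln3 -0.89 ± 0.29. Among inflammatory cytokines and chemokines (22 tested, adjusted p = 0.487), Saa3 had 3.05 ± 1.16 (3.91 without control 2 and 1.76 without Cdo1AKO 2) and Tlr4 -0.45 ± 0.17.

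Among the remaining cell types, markers of adipocyte progenitors and fibroblasts (21 tested, adjusted p = 0.168) had a median of 0.53, and Col1a1 had 1.07 ± 0.49 and Fbn1 1.39 ± 0.65. Both rest on Cdo1AKO 2, without which they were 0.31 and 0.26. For blood endothelium (17 tested, adjusted p = 0.579) Plvap had 0.48 ± 0.15 and Erg 0.44 ± 0.33. For lymphatic endothelium (8 tested, adjusted p = 0.349) Reln had -1.03 ± 0.37 and Lyve1 -0.37 ± 0.15. For erythroid cells (7 tested, adjusted p = 0.231) Bpgm had -0.45 ± 0.17 and Hba-a2 -0.35 ± 0.53. Of the neutrophil and mast cell markers (9 tested, adjusted p = 0.539) S100a9 fell adjusted over the list alone, at 0.0929 ± 0.0811 CPM against 2.01 ± 0.216 CPM (SD, n = 3), and S100a8 had 1.59 ± 0.93 (-0.30 without Cdo1AKO 2). For skin keratinocytes and hair follicles (5 tested, adjusted p = 0.487) Krt79 had 1.51 ± 0.73 (0.25 without Cdo1AKO 2) and Sfn 0.58 ± 0.60. Mammary epithelium (8 tested, adjusted p = 0.202 by camera) was the 1 list that fry called, on the higher side (adjusted p = 0.0352), and Acta2 with 1.49 ± 0.16 and Oxtr with 3.82 ± 0.88 (2.41 without Cdo1AKO 2) rose adjusted over the list alone, while 1 other member fell. The median lay above 0 and the test direction below for adipokines, hypoxia, and neutrophils and mast cells, and the opposite held for B cells.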

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

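The count of 0 changed genes held with edgeR under other scaling factors, other filters, robust estimation, a fold threshold and each sample left out (range 0 to 0), and with limma-voom. On simulated counts edgeR with group only recovered 0 of 67 genes changed 2-fold and 3 of 66 changed 4-fold. A steady count of 0 therefore does not show that few genes differ. The count moved with DESeq2 to 271 (94 higher, 177 lower) and in the authors' deposited comparison to 275. The cause was not tested. Alternatives chosen after seeing the data gave 686 with the lymph node term (375 higher, 311 lower), 590 with a lymph node score as covariate (327 and 263), and 2617 in the 4 libraries with lymph node transcripts (1304 and 1313). Cdo1 passed under these, at -1.76, -1.69 and -2.05, and stayed lower without each sample, from -2.33 to -1.30. With Cdo1AKO 1 and 3 summed and control 3 left out, 0 genes passed with or without the term, in fits with too few samples for this to decide anything. The 17 pathway and RNA quality lists and 8 cell type lists became 0 and 0 with an estimated correlation, 0 and 1 with fry, and 0 and 0 with the lymph node term and an estimated correlation. Without each sample they were 14 to 18 and 7 to 10. Deviations of same-numbered samples from their group means, over all genes, had correlations of -0.66, -0.67 and 0.45. Samples numbered 1, and those numbered 2, differ from each other in lymph node transcripts, which weigh on these values. They therefore cannot decide whether the numbers pair the samples. A replicate block gave 0 genes, 17 and 8 lists, and Cdo1 at -1.77. Signs turned for Lep without Cdo1AKO 2 (-0.070, range to 1.63) and in the 4 libraries (-0.11), S100a8 likewise (-0.30, range to 2.06, and -0.31), Erg without Cdo1AKO 2 (range -0.037 to 0.64), Hba-a2 without control 1 (range -0.92 to 0.16) and Cxcl13 without control 2 (range -1.23 to 0.13). Directions turned for cholesterol synthesis in the 4 libraries (adjusted p = 0.967), ribosomal proteins with the term and summed samples (0.777), and extracellular matrix without Cdo1AKO 2 (0.525, against 1.80e-08 as the lowest with another sample left out) and in the 4 libraries (0.820).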

Other observations

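Cdo1AKO 2 stood apart in genes named after their values were seen. Fasn, the fatty acid synthase, had 2936 CPM there against 264 to 452 CPM in the other 5 libraries, Scd2 747 against 24.7 to 90.7, and Fosb 41.9 against 1.10 to 4.81. Ighm was highest there at 1389 CPM although Cd79a, a B cell receptor subunit, was at 1.54 CPM.

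Of the tests in this part, only the count of changed genes against other splits was chosen before the data were examined; every other test was chosen after the result was seen. The 10 splits of the 6 samples into 3 and 3 are too few for a share under 0.05. The real split gave 0 changed genes by edgeR and the highest other split 0, with 10 splits as large; 17 pathway and RNA quality lists against 15, with 1; 8 cell type lists against 11, with 5; and 271 genes by DESeq2 against 2201, with 2. The split with 2201 genes set control 1, control 3 and Cdo1AKO 2 against control 2, Cdo1AKO 1 and Cdo1AKO 3. That split put the libraries without lymph node transcripts, control 1 and Cdo1AKO 2, on the same side. It also follows the order of the first principal component, at -97.4, 10.2 and -93.4 against 42.4, 68.3 and 69.8. A grouping other than genotype, which follows that component, thus gave a larger count than the real one. It differs from the real split only by exchanging control 2 and Cdo1AKO 2, so the part of its count that follows genotype is not known. With the lymph node term the real split gave 686 genes and the highest of the other splits 0, with 1 of 6 splits as large, again too few for a share under 0.05.

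Lymph node transcripts in 4 of the 6 libraries are consistent with lymph node tissue in the sampled piece, as a hypothesis. T cell and natural killer cell markers, a list not used to separate the libraries, were higher in all 4 libraries than in both others for 18 of 22 genes (81.8%). Lymphoid clusters within the fat were not tested and stay open, as does any effect of genotype on them.

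The lower adipocyte lists may reflect a lower adipocyte share of the RNA. As the only change in cell makeup it would raise the markers of every other cell type alike. Instead 7 Schwann cell and nerve markers fell, and the muscle gene Casq1 rose from 1.57 CPM in controls, each adjusted over the list alone. These values go against it as the only change, but they were known when the comparison was set up, so it was no independent test. Lymph node transcripts also differed between the libraries within both groups. Relative to the mean of the 16 adipocyte markers in each library, 0 differed between the groups at adjusted p under 0.05 by limma, which does not show that they moved alike. The largest relative log2 changes were -1.60 for Cfd, 1.32 for Lep and -1.26 for Adrb3. A lower adipocyte share together with changes in other cell types, and lower expression per adipocyte, cannot be told apart with 3 libraries per group.

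Some libraries may share source material, as a hypothesis, which would leave fewer independent samples than libraries, while the 686 genes called with the lymph node term treat all as independent. For immunoglobulin V genes, whose use differs between animals, both same-group pairs with lymph node transcripts were about equally alike, at 1.93 times the counting variance for Cdo1AKO 1 and 3 and 1.79 times for control 2 and 3, against at least 6.18 times between the groups among these 4 libraries. Over all other genes control 3 differed from the best mixture of controls 1 and 2, with weight 0.470 for control 1, by a median of 3.23 times the counting variance, against 6.93 for control 2 alone and 4.86 for control 1 mixed with Cdo1AKO 1; on the V genes the mixture (1.93 times) could not be tested, since control 1 held 83 V counts against 5310 in control 2. The bound set for a shared source lay below the counting variance itself and a fitted weight always comes as close as either part, so a shared animal, a mixture, litter mates and a shared exposure stay open. Lymph node content alone was tested on 102 genes with mean CPM of at least 5. They were at least 2-fold higher in control 1 than in control 2 after each library was scaled to its mean adipocyte marker level. On these scaled values control 3 lay between controls 1 and 2 in 96.1% of the genes. Cdo1AKO 1 and 3 each did in 71.6% and Cdo1AKO 2 in 37.3%, so the test does not decide it.

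Of 14 other tested genes starting within 2 Mb of Cdo1, 0% were called with the lymph node term (upper exact 95% limit 23.2%), against 4.13% of all genes, too few genes to decide on a passenger region.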
